A study of Mus musculus with 3 samples.

How the data were processed

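Livers of mice were profiled by droplet single-cell RNA sequencing (10x Genomics Chromium, 3' chemistry, per the labels' protocols) in 3 libraries, 1 library per group. FL_control is the library labelled as a floxed Gsdmd animal without irradiation, FL_IR the library labelled as a floxed animal after irradiation, and dHep_IR the library labelled as a hepatocyte deletion of Gsdmd after irradiation. The genotype tag of dHep_IR names a knockout without naming hepatocytes. The series' design text gives a dose of 30 Gy and a harvest 7 days later. It does not say which part of the body was exposed or which exons were removed. Whether a library came from 1 animal or from a pool is not given in the sources used here.

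The deposited files hold raw UMI counts per gene and cell barcode, with no normalization, as whole numbers, and the authors made them with Cell Ranger 6.1.1 against the mm10 build, per the submitters' processing notes, which also name CASAVA 1.8 and Seurat 4.0.3. The annotation version is not given in the sources used here. Each library listed the same 31253 genes. The libraries held 7393 barcodes for FL_control, 7265 for FL_IR and 8214 for dHep_IR, with 52858425, 59228905 and 78694038 UMIs and a median of 5423, 7208 and 7573 UMIs per barcode. Free RNA was not removed.

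Cells with at least 500 UMIs, at least 250 genes and a mitochondrial share of at most 25 percent were kept, which left 6618, 6780 and 7552 cells. Doublets were marked per library with Scrublet as built into scanpy 1.11.5, at an expected rate of 6 percent. It removed 154, 235 and 293 cells, or 2.33, 3.47 and 3.88 percent, and 6464, 6545 and 7259 cells remained. Counts were log-normalized, and 2000 variable genes, 30 principal components and 15 neighbours were used, with all libraries clustered together by the Leiden method at resolution 1 (igraph 0.11.9) and without batch integration. This gave 31 clusters. A cluster was called X-like from fixed markers, at least 3 of them detected and at least 1 among its 10 leading genes, and stayed unnamed where the markers of another class led as strongly, where markers of another lineage stood among its leading genes, or where these conditions were not met. The scoring details were set after the clusters had been seen. Sinusoidal and vascular endothelial clusters were joined into 1 endothelial-like class. The monocyte-like class holds clusters 7, 10 and 27 and takes in monocyte-derived macrophages.

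With 1 library per group no test between groups is possible, cells are not replicates, and no p-value is given. Raw UMI counts were summed per library and class and expressed as counts per 1000000 UMIs of the class total (CPM). Intervals are 95 percent intervals, exact Poisson for a sum, exact Clopper-Pearson for a share and exact conditional for a ratio, and they cover counting error only. Log2 ratios had a prior count of 0.5 added on each side. A library at 0 was given a floor of 3 counts. A fold written as at least is taken at that floor. The lower bound of its 95 percent interval is smaller, for example 580 in place of 715 for Cxcl9 in monocyte-like cells of FL_IR against FL_control. Classes with at least 50 cells in both libraries were compared: endothelial-like, neutrophil-like, monocyte-like, Kupffer-like and T-like cells. The comparisons were FL_IR against FL_control and dHep_IR against FL_IR, with dHep_IR against FL_control as a further value, for which NK or ILC1-like cells also qualify.

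The rule for named genes was fixed before the data were examined, as were the cell filters, the markers, the 27 gene lists, the comparisons and most alternatives. It names Gsdmd; for each comparison and class the 2 genes with the highest and the 2 with the lowest ratio among genes with at least 100 UMIs, a UMI in at least 10 percent of cells of 1 library, an interval excluding 1 and at least 0.25 times the highest CPM of any compared class, leaving out mitochondrial, ribosomal protein, haemoglobin, antigen receptor, sex-linked and unnamed genes and the markers of all classes; up to 4 members with the largest ratio of each list described; and sex-linked genes and markers of other classes as checks. For a list with at least 5 members of at least 20 UMIs, the median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries.

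The statistics were tested on simulated Poisson counts drawn from the real class sums with 200 changed genes. These counts had no variation between cells or animals, so the test checks the calculation and says nothing about such variation. For endothelial-like cells of FL_IR against FL_control, over 12484 genes, 95.4 percent of the intervals of unchanged genes held the true ratio, and the median recovered log2 ratio was 1.00 for a 2-fold and 1.98 for a 4-fold change. For neutrophil-like cells of the same libraries, over 9402 genes, the values were 96.8 percent, 0.91 and 1.94. The interval excluded 1 on the true side for 61.9 percent of 2-fold changes there, against 91.9 percent in endothelial-like cells. Alternatives covered doublets, the cell filter, the clustering, the make-up of the monocyte-like class, the denominator of shares, the weighting of cells, the minimum count of list members and the scaling, including TMM factors from edgeR 4.0.16 in R 4.3.3. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.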

Results

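Whole-transcriptome UMI counts of single liver cells were compared between 3 libraries, 1 per group, so no value below has a spread between animals and no test between groups was possible. The library labelled FL_control (unirradiated, floxed Gsdmd) had 52858425 UMIs over 7393 barcodes, the library labelled FL_IR (irradiated, floxed) 59228905 over 7265, and the library labelled dHep_IR (irradiated, hepatocyte deletion of Gsdmd) 78694038 over 8214. After filtering, 6464, 6545 and 7259 cells were kept. Every interval is a 95 percent interval that covers counting error only. Classes are named by markers and written as X-like. FL_IR against FL_control asks about irradiation, and dHep_IR against FL_IR about the deletion under irradiation, as the labels state the groups. Both comparisons contain FL_IR, so values that go opposite ways in them can arise from that shared library. Levels of dHep_IR beside FL_control are given for some genes below. How far the medians of the fixed gene lists arise in this way was not tested.

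Gsdmd, the pore-forming protein of pyroptosis and the gene the labels say was deleted in hepatocytes of dHep_IR, was lower in the library labelled FL_IR than in both others. Gsdmd (ENSMUSG00000022575) lies on the + strand of chromosome 15 from 75862327 to 75867408 (GRCm38). Over all kept cells the library labelled FL_IR, a floxed animal as FL_control is, had 391 Gsdmd UMIs, against 1760 in FL_control and 2624 in dHep_IR. Its level was 7.20 CPM (6.50 to 7.95), 5.06-fold lower (4.53 to 5.66) than the 36.4 CPM of FL_control. The library labelled dHep_IR had 36.8 CPM, 5.11-fold above FL_IR (4.59 to 5.70) and 1.01 times FL_control (0.951 to 1.07).

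The low Gsdmd of the library labelled FL_IR was seen in each of the 5 classes compared. In FL_control, FL_IR and dHep_IR, endothelial-like cells had 26.0, 9.26 and 24.3 CPM of Gsdmd, and neutrophil-like cells 78.6, 6.31 and 37.1. Monocyte-like cells had 66.9, 6.45 and 53.3 CPM, and Kupffer-like cells 58.1, 8.05 and 36.1. T-like cells had 32.0, 2.68 and 20.02 CPM, with 2 UMIs in FL_IR. Against FL_control the level of dHep_IR was 0.934 times (0.823 to 1.06) in endothelial-like, 0.472 times (0.393 to 0.571) in neutrophil-like and 0.797 times (0.680 to 0.938) in monocyte-like cells. It was 0.622 times (0.501 to 0.766) in Kupffer-like and 0.627 times (0.418 to 0.915) in T-like cells. The ratio over all kept cells, 1.01, stood above that of each of these classes, whose shares differ between the libraries, and the median log2 ratio of all genes in neutrophil-like cells was itself -0.66. For FL_IR against FL_control the log2 ratio of Gsdmd in neutrophil-like cells, -3.64, was -2.99 with TMM factors, and that in Kupffer-like cells, -2.82, was -3.46 as a mean of per-cell CPM. As such means the log2 ratios of dHep_IR to FL_IR were 2.92 in place of 2.14 in Kupffer-like and 1.995 in place of 2.60 in T-like cells. Hepatocyte-like cells, the cells the labelled deletion concerns, numbered 104, 43 and 8 with 22, 2 and 1 Gsdmd UMIs, too few to check a deletion in dHep_IR. A 3' tag outside the deleted part would check nothing, and the sources used here do not say which exon is floxed. Every direction below is therefore a direction between libraries as labelled.

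**Figure D1:**
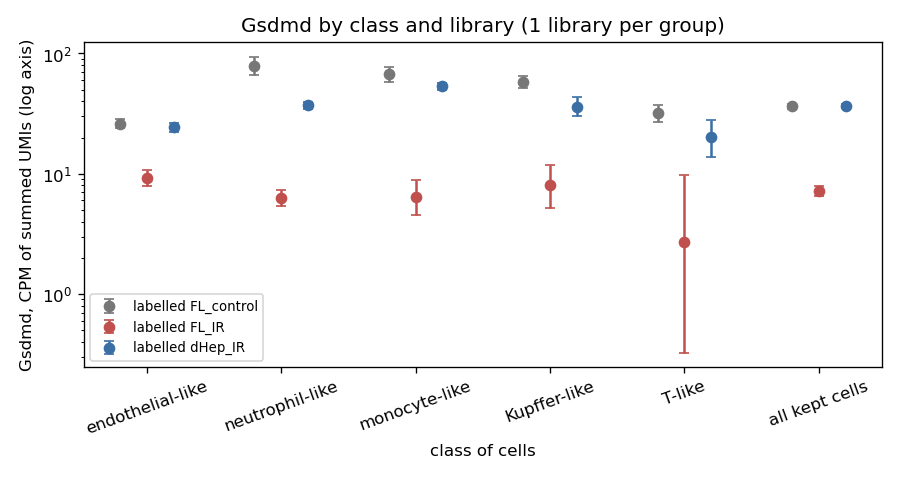
Gsdmd level (CPM of summed UMIs, log axis) by class of cells in the libraries labelled FL_control, FL_IR and dHep_IR; points are levels and bars exact Poisson intervals. Over all kept cells FL_IR lies at 7.20 CPM, below the 36.4 of FL_control and the 36.8 of dHep_IR.

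The sex-linked genes gave the same male pattern in the 3 libraries. Xist, expressed from the inactive X chromosome, had 1, 7 and 4 UMIs in FL_control, FL_IR and dHep_IR. The Y-linked Ddx3y had 124, 104 and 93.3 CPM.

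In the library labelled FL_IR against FL_control, neutrophil-like cells took a larger share and lymphocytes a smaller one. Neutrophil-like cells made up 35.8 percent of kept cells (34.6 to 37.0) against 7.10 percent (6.49 to 7.75), a 5.04-fold higher share (4.56 to 5.58). B-like cells were at 0.321 percent against 21.9 percent, 68.3-fold lower (44.5 to 111). T-like cells were at 1.76 against 10.2 percent, 5.82-fold lower (4.77 to 7.16), and NK or ILC1-like cells at 0.428 against 2.24 percent, 5.24-fold lower (3.48 to 8.17). No pDC-like cell was found among the 6545 cells of FL_IR, which allows a share of up to 0.0563 percent, against 2.12 percent in FL_control. The share was at least 37.1-fold lower by the interval, and 46.2-fold lower at the floor of 3 counts.

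Among the other classes of this comparison, monocyte-like cells were at 7.26 against 4.02 percent, 1.804-fold higher (1.55 to 2.11). Kupffer-like cells, the resident liver macrophages, were at 6.89 against 8.73 percent, 1.27-fold lower (1.12 to 1.44). Endothelial-like cells were at 38.8 percent in both libraries, which depends on which shallow clusters were named. Cluster 8, with a median of 2067 UMIs and endothelial as its best class, stayed unnamed. It held 11 cells of FL_control, 468 of FL_IR and 530 of dHep_IR. Cluster 16, with a median of 1817 UMIs, was named endothelial-like and held 314, 4 and 7 cells. With cluster 8 counted as endothelial-like the log2 ratio of the share was 0.24 in place of 0.0003. Hepatocyte-like cells were at 0.657 against 1.61 percent and cholangiocyte-like cells at 0.489 against 0.696 percent, and 7.62 against 2.58 percent stayed unnamed. The median mitochondrial share of hepatocyte-like cells was 0.329 percent in FL_control, 0.0420 in FL_IR and 14.1 in dHep_IR. Their shares and levels may therefore compare unlike cells between libraries. Different clusters held a class in the 2 libraries: endothelial-like cells of FL_control lay in clusters 2, 16 and 24 and those of FL_IR in 0, 5, 6 and 14, with cluster 23 shared. Neutrophil-like cells lay in cluster 15 against 1 and 3, Kupffer-like cells in 11 against 9, and monocyte-like cells in 10 and 27 against 7. A cluster at resolution 2 with markers of dendritic cells held 92 of the 260 monocyte-like cells of FL_control, 4 of the 475 of FL_IR and 97 of the 1169 of dHep_IR. Without these dendritic cells the log2 ratio of the monocyte-like share was 1.47 in place of 0.85, at resolution 2 it was 1.87, and without cluster 10 it was 3.41. Without cluster 10 the control keeps 41 monocyte-like cells, fewer than the 50 asked of a class, so values of FL_IR against FL_control without it rest on few cells. Dissociation sets shares as well, and with 1 library per group it cannot be separated from the group.

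Markers of red blood cells and signs of cell quality differed between the libraries too, beside every gene group below. Over all kept cells the haemoglobin transcript Hbb-bs was at 600 CPM in FL_control, 2.28 in FL_IR and 18.3 in dHep_IR, and Hba-a1 at 292, 1.64 and 10.4 CPM. In endothelial-like cells Hbb-bs was at 442, 4.39 and 5.61 CPM. The median mitochondrial share of kept cells was 4.56, 1.71 and 2.78 percent. Mitochondrial transcripts took 5.43, 2.43 and 3.30 percent of UMIs in endothelial-like cells and 5.001, 4.88 and 5.52 percent in Kupffer-like cells.

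**Figure D2:**
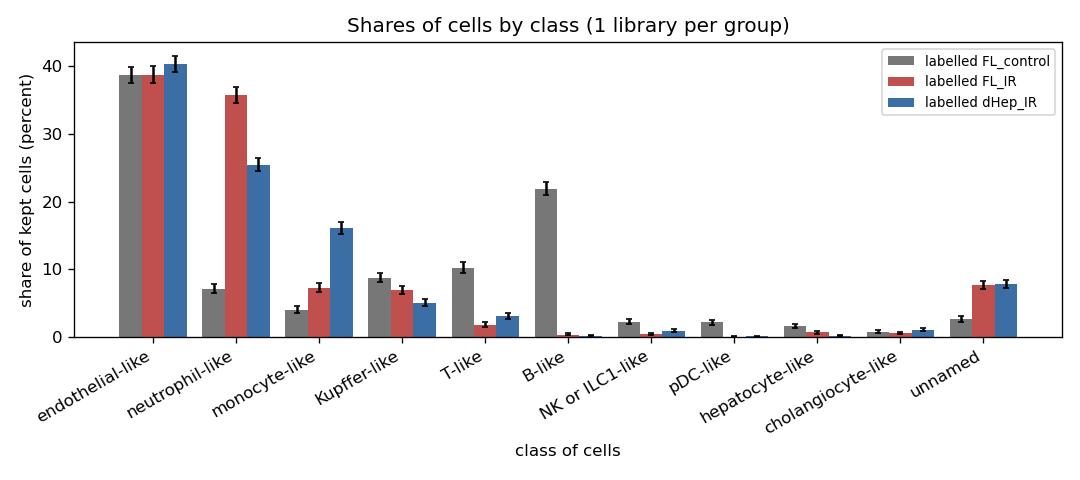
Share of kept cells (percent) by class in the libraries labelled FL_control, FL_IR and dHep_IR; bars start at 0 and error bars are exact Clopper-Pearson intervals. Neutrophil-like cells are at 7.10, 35.8 and 25.5 percent and B-like cells at 21.9, 0.321 and 0.138 percent.

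Targets of p53, the transcription factor activated by DNA damage, were higher in endothelial-like cells of the library labelled FL_IR than of FL_control. Their median log2 ratio was 2.52 (percentile 100 among matched lists), with 22 of 23 measured members higher. Gdf15 was 173-fold higher (103 to 317), Ckap2 58.7-fold, Phlda3 24.5-fold and Tnfrsf10b 23.4-fold. In Kupffer-like cells the median was 1.10 and 20 of 21 members were higher, among them Phlda3 (43.6-fold), the cell-cycle inhibitor Cdkn1a (28.9-fold) and Trp53inp1 (10.4-fold), while Ckap2 was at least 4.99-fold lower. T-like cells had a median of 0.39 and monocyte-like cells of -0.16, which was 0.02 with TMM factors. In neutrophil-like cells it was -1.11, where the median of all genes was itself -0.58, and it turned to 0.59 with doublets kept. There Pmaip1 was 13.8-fold and Plk2 6.32-fold lower. TMM factors add 0.65 to every log2 ratio of neutrophil-like cells in this comparison, which puts the median of all genes at 0.07 and that of p53 targets at -0.46, and they add 0.18 in monocyte-like cells.

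Interferon-stimulated genes were lower in all 5 classes of the library labelled FL_IR than of FL_control. The median log2 ratio was -2.47 in endothelial-like, -3.79 in neutrophil-like, -2.92 in monocyte-like, -1.91 in Kupffer-like and -0.61 in T-like cells, the last -0.76 with members at 0 set to their bound. The percentile among matched lists was 0 in each class. The neutrophil-like value stands beside a median of all genes of -0.58, and was -3.14 with TMM factors and -2.99 over members with at least 100 UMIs. The monocyte-like value was -2.09 without cluster 10 and -3.31 without dendritic cells. All 32 measured members were lower in endothelial-like cells, among them Ifit3b (36.8-fold), Ifi44 (32.6-fold), Ifit3 (18.8-fold) and Zbp1 (16.1-fold). In monocyte-like cells all 31 were lower, with Gbp3 at 54.5-fold (25.9 to 137) and Ifit2 at 118-fold (32.1 to 989, from 2 UMIs). Cxcl9, a chemokine induced by interferon gamma, was not detected in monocyte-like cells of FL_IR against 384 CPM in FL_control, at least 715-fold lower, and without cluster 10 at least 84.7-fold lower.

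MHC class II genes, which present antigen to helper T cells, were also lower in the library labelled FL_IR. The median was -5.45 in monocyte-like, -3.68 in Kupffer-like, -4.87 in endothelial-like, -6.25 in neutrophil-like and -4.94 in T-like cells, the last -3.20 with members at 0 set to their bound. With doublets kept the median was -6.46 in endothelial-like, -6.99 in neutrophil-like and -6.26 in T-like cells, and with TMM factors -5.60 in neutrophil-like cells. Over members with at least 100 UMIs the T-like median was -5.64, and with the stricter filter -5.61. Neutrophils and T cells make little of these transcripts, and B-like cells, which make much, were 21.9 percent of FL_control. In monocyte-like cells all 7 members were lower: Ciita, the master regulator of the class, 146-fold (56.2 to 538), H2-Eb1 57.5-fold, H2-Ab1 56.8-fold and H2-Aa 43.8-fold. H2-Ob, of the same pathway, was at least 167-fold lower there. Dendritic cells, which make much of these transcripts, were 92 of the 260 control cells of the class and 4 of the 475 of FL_IR. Without them the median was -5.29, with H2-Eb1 71.2-fold, H2-Ab1 56.3-fold and H2-Aa 39.1-fold, Ciita at least 67.3-fold and H2-Ob at least 26.7-fold lower, the last at least 28.9-fold at resolution 2. Without cluster 10 the median was -6.00, with 0 UMIs of Ciita and of H2-Ob in FL_IR against 2 of each in the 41 control cells left. There H2-Ab1, H2-Eb1, H2-Aa and Cd74 were still lower, by 38.0-fold (30.3 to 47.8) or more, while H2-DMa was at 0.903 times (0.547 to 1.60) and H2-DMb1 at 0.588 times (0.299 to 1.32), with intervals that include 1.

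Genes of the acute phase and of immature neutrophil granules were higher in the library labelled FL_IR. The acute-phase median was 2.55 in Kupffer-like, 1.97 in monocyte-like, 1.85 in endothelial-like, 1.51 in T-like and 0.25 in neutrophil-like cells. It was 1.29 in monocyte-like cells without cluster 10 and 0.90 in neutrophil-like cells with TMM factors. Most of these are hepatocyte transcripts, and Lcn2 is a neutrophil one, and free RNA was not removed. Abundant hepatocyte transcripts took 1.77 percent of endothelial-like UMIs against 0.591 percent, 3.80 against 3.097 percent in Kupffer-like and 0.779 against 0.391 percent in monocyte-like cells. They took less in neutrophil-like (0.0726 against 0.193 percent) and T-like cells (0.0905 against 0.0984 percent). That list holds Mt1 and Mt2, which in endothelial-like cells were at 11828 and 4600 CPM against 651 and 156. These genes made up most of the endothelial-like share in FL_IR, so it is no measure of hepatocyte RNA there. In monocyte-like cells Mt1 was at 2034 CPM against 157. Apoe, another member of that list, was among the leading genes of Kupffer-like clusters 9 and 11. The monocyte-like and Kupffer-like shares are therefore no clean measure of hepatocyte RNA either. Lcn2 was 154-fold higher (59.7 to 569) in Kupffer-like cells, at 106 CPM, while neutrophil-like cells of FL_IR had 12037 CPM, endothelial-like cells 122 and T-like cells 73.8, so its Kupffer-like level lay between those of endothelial-like and T-like cells. Saa3 was 25.8-fold higher in Kupffer-like cells, at 124 CPM beside 5.82 in endothelial-like and 9.39 in T-like cells of FL_IR. Monocyte-like cells had more Saa3 (157-fold, 119 to 213), a log2 ratio of 7.28 that was 6.02 as a mean of per-cell CPM and 6.69 at resolution 2. In neutrophil-like cells the granule median was 3.98, with Ngp 199-fold, Chil3 196-fold, Camp 136-fold and Ltf 107-fold higher. The same granule list was higher in endothelial-like (5.84), Kupffer-like (4.04), T-like (3.28) and monocyte-like cells (3.03), and S100a8 and S100a9 took 0.106 percent of endothelial-like UMIs against 0.00436 percent, 0.213 against 0.00558 percent in Kupffer-like, 0.0909 against 0.00641 percent in T-like and 0.855 against 0.00881 percent in monocyte-like cells. With doublets kept that list was at 7.12 in Kupffer-like, 6.95 in T-like and 4.61 in monocyte-like cells, as a mean of per-cell CPM at 0.99, 2.45 and 2.31, and in endothelial-like cells at 4.94 with the stricter filter. The list of mature neutrophil activation had a median of -2.95 in neutrophil-like cells, with Ptgs2 66.9-fold, Cd274 33.0-fold, Ccl4 21.7-fold and Il1rn 16.4-fold lower. Dissociation stress genes, which handling of cells induces, were lower in the same cells, with a median of -1.27 (percentile 1.86) and 15 of 16 members lower, among them Atf3 49.2-fold, Dusp1 9.55-fold and Fos 9.32-fold. With TMM factors that median was -0.62.

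Sinusoidal identity genes were lower in endothelial-like cells of the library labelled FL_IR, with a median of -1.28 and 15 of 18 members lower. Ehd3 was 9.70-fold, Dnase1l3 7.75-fold and Mrc1 4.19-fold lower, while Lyve1 was 4.76-fold higher. The same list had medians of -4.66 in neutrophil-like, -3.87 in monocyte-like, -1.74 in T-like and -1.50 in Kupffer-like cells, and the neutrophil-like value turned to 0.92 with doublets kept, when the monocyte-like one was -1.88 and the T-like one -2.76. As a mean of per-cell CPM the neutrophil-like value was -3.68. Endothelial activation genes had a median of 0.06 and went both ways, with Selp 10.2-fold and Cd34 9.96-fold higher and Cxcl9 57.7-fold lower. In Kupffer-like cells proliferation genes had a median of -3.12, with Ube2c at least 39.6-fold lower and Top2a 86.7-fold lower (15.3 to 3444, from 1 UMI). Kupffer identity genes had a median of -0.05 and a mean of 0.23 there, with Marco 14.2-fold higher and Folr2 2.60-fold lower. In T-like cells cytotoxic effector genes had a median of -1.23, with Ccl4 15.7-fold, Ccl3 9.94-fold and Gzma 4.80-fold lower.

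Inflammasome genes were lower in neutrophil-like cells of the library labelled FL_IR, with a median of -2.58, which was -1.75 over members with at least 100 UMIs, and 12 of 13 members lower. The median of all genes was -0.58 and that of dissociation stress genes -1.27 there, cGAS-STING genes were at -1.10 (percentile 10.29), or -1.02 with members at 0 set to their bound, and lipid-associated macrophage genes at -1.64. In monocyte-like cells lipid-associated macrophage genes were at -1.60 with 9 of 14 members lower, which was -0.93 over members with at least 100 UMIs and turned to 0.26 without cluster 10. Inflammatory genes were at 0.88 in Kupffer-like, 0.58 in endothelial-like, 0.02 in monocyte-like, -2.01 in neutrophil-like and -0.02 in T-like cells, while the mean of the list was -0.09 in endothelial-like and -0.80 in monocyte-like cells. In Kupffer-like cells inflammasome genes were at -0.23, cGAS-STING genes at -0.57, lipid-associated macrophage genes at -0.72 and apoptosis genes at 0.19. In monocyte-like cells NRF2 genes were at 0.91 and monocyte recruitment genes at 0.78, with a mean of -0.04 and a median of 2.78 without cluster 10. Naive and memory genes were at -0.02 and checkpoint genes at -0.13 in T-like cells. In endothelial-like cells dissociation stress genes were at -0.18, which was 0.0154 as a mean over cells, stellate and matrix genes at -0.09 with a mean of 0.32, and fatty acid genes at -0.16. Dissociation stress genes were at 0.21 in Kupffer-like cells, -0.00158 as a mean over cells, and at 0.14 in T-like cells. In monocyte-like cells they were at -0.08, which was 0.10 with TMM factors, 0.0632 with the stricter filter and -0.80 without cluster 10. The hepatocyte lists could be read only as transcripts outside hepatocyte-like cells: in endothelial-like cells pericentral genes were at -1.56, periportal genes at 0.13 with a mean of -0.32, bile acid genes at -1.19 and abundant hepatocyte transcripts at -0.33. The last median weighs each member alike, while the share of UMIs of that list, mostly Mt1 and Mt2 in FL_IR, went the other way (1.77 against 0.591 percent).

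Of the genes named by rule, Ctsj was 1034-fold (525 to 2397) and the transcription factor Zbtb16 630-fold (246 to 2313) higher in endothelial-like cells of the library labelled FL_IR. In neutrophil-like cells Ggt1 was at least 56.5-fold and Cstdc5 263-fold higher, and Prr5l was 213-fold lower. Scrg1 was 221-fold higher in monocyte-like cells (39.5 to 8757, from 1 UMI in FL_control), 128-fold without dendritic cells (22.8 to 5048), 108-fold at resolution 2 (19.2 to 4259) and at least 6.98-fold without cluster 10. In Kupffer-like cells Ttc39c was 71.8-fold and Ccl9 71.4-fold higher, and Ptgis 64.5-fold lower. As means of per-cell CPM the log2 ratios were 8.22 in place of 9.13 for Zbtb16, 5.19 in place of 6.15 for Ccl9 and -5.21 in place of -5.88 for Ptgis, and with doublets kept that of Prr5l was -6.40 in place of -7.67. In T-like cells Fkbp5 was 5.63-fold and Socs3 4.93-fold higher, and the cytokine Il4 at least 9.91-fold lower, which with doublets kept was 15.2-fold (4.15 to 126, from 2 UMIs). Mup11, a hepatocyte transcript, was lower in endothelial-like (192-fold), neutrophil-like (387-fold), Kupffer-like (at least 51.2-fold) and T-like cells (at least 13.6-fold), and Mup7 at least 83.3-fold lower in endothelial-like cells. Hepatocyte-like cells had 12582 CPM of Mup11 in FL_control and 30.5 in FL_IR, over 104 and 43 cells with median mitochondrial shares of 0.329 and 0.0420 percent.

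In the library labelled dHep_IR against FL_IR, monocyte-like cells took a larger share and neutrophil-like cells a smaller one. Monocyte-like cells were at 16.1 percent (15.3 to 17.0) against 7.26 percent, 2.22-fold higher (1.99 to 2.47). Neutrophil-like cells were at 25.5 against 35.8 percent, 0.712 times (0.669 to 0.757), and Kupffer-like cells at 5.001 against 6.89 percent, 0.726 times. T-like cells were at 3.06 against 1.76 percent, 1.74-fold higher (1.38 to 2.20), and NK or ILC1-like cells at 0.895 against 0.428 percent. Endothelial-like cells were at 40.3 against 38.8 percent, 1.04 times (0.986 to 1.10). The monocyte-like excess lay largely in cluster 10, with 544 cells against 30, while cluster 7 had 624 against 445, and without cluster 10 the log2 ratio was 0.34 in place of 1.15. Within the other classes cells lay in different clusters as well: 1746 against 528 endothelial-like cells in cluster 0 and 210 against 1229 in cluster 5, and 489 against 1221 neutrophil-like cells in cluster 3 and 187 against 31 in cluster 18. B-like cells were 10 against 21 cells, hepatocyte-like cells 0.110 against 0.657 percent and cholangiocyte-like cells 1.05 against 0.489 percent, with 3 pDC-like cells against 0 and 7.81 against 7.62 percent unnamed.

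Monocyte-like cells of the library labelled dHep_IR had more interferon-stimulated, MHC class II and proliferation transcripts than those of FL_IR. The interferon-stimulated median was 1.23 with all 31 measured members higher, among them Gbp3 (26.0-fold, 12.5 to 64.9) and Ifit1 (80.5-fold, 22.2 to 667, from 2 UMIs). Without cluster 10 this median was -0.01. Cxcl10, an interferon-induced chemokine, was 44.8-fold (34.6 to 59.0) and Ifi205 32.7-fold (19.8 to 58.6) higher. In FL_control, FL_IR and dHep_IR, Cxcl10 was at 207, 10.4 and 465 CPM and Ifi205 at 147, 2.69 and 87.9 CPM. Ifi205 in dHep_IR thus lay below FL_control. Without cluster 10 Cxcl10 and Ifi205 were 3.57-fold (2.62 to 4.95) and 3.69-fold (1.56 to 10.6) higher. With doublets kept the log2 ratio of Cxcl10 was 4.88 in place of 5.47. MHC class II genes had a median of 3.63, with Ciita 17.6-fold, H2-Eb1 12.9-fold and H2-Ab1 12.8-fold higher. Of the monocyte-like cells, 97 of dHep_IR and 4 of FL_IR were dendritic, and 544 and 30 lay in cluster 10. Without dendritic cells the median was 3.90, with H2-Ab1 19.9-fold and H2-Eb1 19.2-fold higher. Without cluster 10 it was 1.16 over 6 measured members, with no UMI of Ciita in either library. There H2-Ab1 was 6.96-fold (2.84 to 22.1), H2-Eb1 3.25-fold (1.36 to 9.42), H2-Aa 2.59-fold (1.34 to 5.49) and Cd74 2.01-fold (1.65 to 2.48) higher, while H2-DMa was at 0.990 times (0.861 to 1.14) and H2-DMb1 at 0.791 times (0.619 to 1.01). Proliferation genes had a median of 1.83, with Ccnb2 35.5-fold (12.0 to 173, from 3 UMIs) and Birc5 12.9-fold higher.

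In the other classes of dHep_IR against FL_IR the interferon-stimulated medians were -0.04 in endothelial-like, -0.06 in Kupffer-like, 0.27 in neutrophil-like and 0.29 in T-like cells. Among matched lists the neutrophil-like value had percentile 100 and the T-like value 98.93. In neutrophil-like cells 7 of 31 members were at least 2-fold higher and 0 at least 2-fold lower, counting those with an interval that excludes 1, and the median was 0.71 as a mean of per-cell CPM and 0.0639 over members with at least 100 UMIs. The endothelial-like and Kupffer-like values had means of 0.05 and 0.07 and were 0.04 and 0.09 with TMM factors. MHC class II genes were at 2.84 in endothelial-like, 2.28 in neutrophil-like (1.60 with doublets kept) and 1.69 in Kupffer-like cells. Some members were at least 2-fold lower in FL_IR than in both other libraries in all 5 classes. For these the T-like log2 ratios of FL_IR to dHep_IR were -4.43 (H2-Ab1), -4.65 (H2-Aa), -3.20 (H2-Eb1) and -3.10 (Cd74). Neutrophils and T cells make little of these transcripts, and free RNA was not removed. The endothelial-like and neutrophil-like values compare cells that lay in part in different clusters, as given with the shares. Inflammatory genes were higher in all 5 classes, with medians from 0.36 in endothelial-like to 0.83 in Kupffer-like cells, where Ccl7 was 9.17-fold and Il1b 3.66-fold higher. The monocyte-like median of that list, 0.74, turned to -0.34 without cluster 10. Proliferation genes were at 1.25 in T-like cells, where the histone gene Hist1h2ap was 29.3-fold higher (13.4 to 80.4). Its level there was 104, 8.05 and 236 CPM in FL_control, FL_IR and dHep_IR. The p53 medians were -0.10 in endothelial-like, -0.01 in neutrophil-like, 0.14 in monocyte-like, -0.40 in Kupffer-like and 0.11 in T-like cells. The neutrophil-like one was 0.08 with TMM factors and the monocyte-like one -0.0516 without cluster 10. Dissociation stress genes were lower in Kupffer-like cells, at -0.83, with Fosb 3.27-fold and Fos 2.83-fold lower, and were at -0.57 in monocyte-like and -0.43 in neutrophil-like cells.

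Hepatocyte transcripts differed in several classes between the irradiated libraries. Saa2, an acute-phase transcript, was 13.8-fold higher in endothelial-like, 12.6-fold in neutrophil-like, 23.7-fold in Kupffer-like and 27.7-fold (9.32 to 135) in T-like cells of the library labelled dHep_IR, and Saa1 6.55-fold higher in endothelial-like cells. Hepatocyte-like cells had 42448 CPM of Saa2 in dHep_IR, over 8 cells, and 1765 in FL_IR. Their median mitochondrial share was 14.1 percent in dHep_IR and 0.0420 percent in FL_IR, so these levels may compare unlike cells. The list of abundant hepatocyte transcripts had a negative median in all 5 classes: -1.62 in endothelial-like, -1.98 in neutrophil-like, -2.05 in monocyte-like, -1.35 in Kupffer-like and -0.65 in T-like cells. The last was 0.33 over members with at least 100 UMIs, and the neutrophil-like one -1.38 as a mean of per-cell CPM. The share of UMIs that the list took was nevertheless higher in endothelial-like (2.35 against 1.77 percent) and T-like cells (0.103 against 0.0905 percent), and lower in the other classes. Its members Mt1 and Mt2 were at 15834 and 6714 CPM against 11828 and 4600 in endothelial-like cells. In T-like cells they were at 535 and 217 CPM against 164 and 48.3. The higher share in these classes is therefore no measure of hepatocyte RNA. Ahsg was 5.50-fold and Apoa2 5.30-fold lower in endothelial-like cells, 5.45-fold and 5.22-fold lower in monocyte-like cells, and Rbp4 12.5-fold and Apoa2 8.19-fold lower in neutrophil-like cells. In Kupffer-like cells Mthfd2 was 18.5-fold higher (9.55 to 41.2) and Kcnj16 6.79-fold and Fbxo32 6.72-fold lower. In FL_control, FL_IR and dHep_IR these cells had 5.86, 2.90 and 53.7 CPM of Mthfd2 and 42.4, 108 and 15.8 of Kcnj16. Fbxo32 was at 16.0, 82.8 and 12.3 CPM. In T-like cells Il17ra was 2.51-fold and Lyst 2.37-fold lower.

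**Figure D3:**
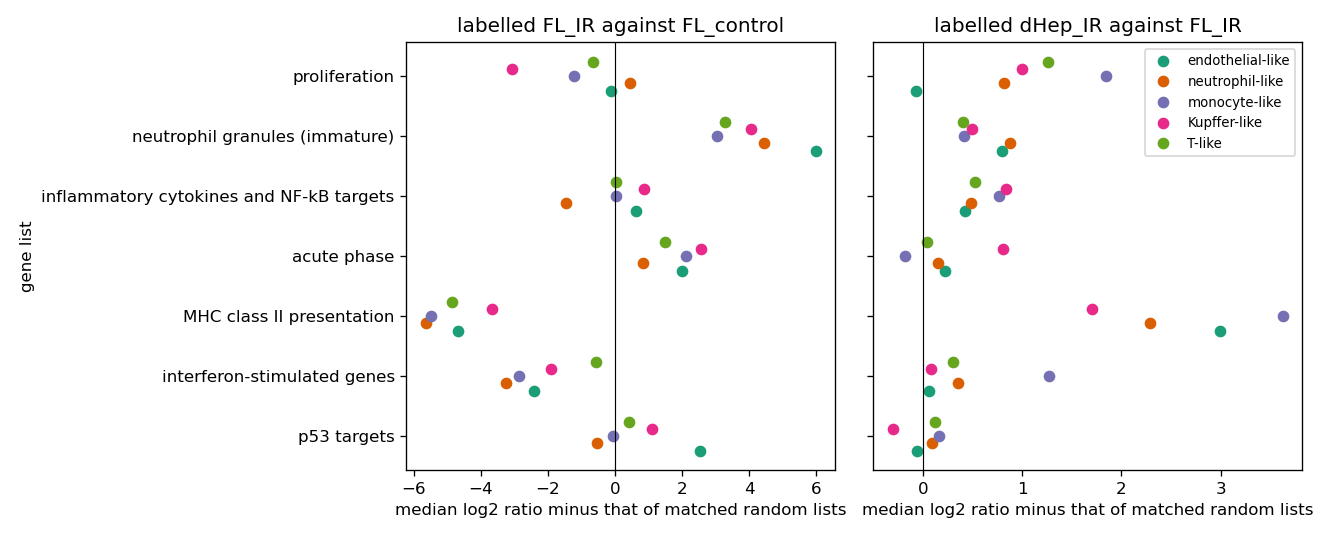
Median log2 ratio of 7 gene lists minus that of matched random lists, by class, for the libraries labelled FL_IR against FL_control (left) and dHep_IR against FL_IR (right); each point is 1 class. Interferon-stimulated genes lie below 0 in all classes on the left, and on the right the highest is that of monocyte-like cells.

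As a further value, the library labelled dHep_IR was compared with FL_control. Neutrophil-like cells had a 3.59-fold higher (3.24 to 3.98), monocyte-like cells a 4.004-fold higher (3.50 to 4.60) and T-like cells a 3.34-fold lower (2.87 to 3.91) share. B-like cells were 159-fold lower (86.2 to 332).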

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

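The alternative that counts cluster 8 as endothelial-like and those without cluster 10 or without dendritic cells were chosen after the data were seen. No paired analysis was possible because each group has 1 library. All 64 alternative values of Gsdmd and all 250 of the other named genes kept their sign, as did 85 of 86 shares, the exception being an endothelial-like share near 0, and 1366 of 1461 list medians. Of the named-gene values 18 moved beyond their counting interval, and of the list medians 233. For 25 of the list medians the change of sign concerned a value whose counting interval excluded 0. Values are log2, and the cause of a change was not tested. A is FL_IR against FL_control and B is dHep_IR against FL_IR, as labelled. Clustering each library on its own gave no value for the monocyte-like and NK or ILC1-like shares in A or the B-like and NK or ILC1-like shares in B, since a library then had 0 such cells.

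Monocyte-like share in A: 1.87 at resolution 2, 1.20 with the looser mitochondrial filter, 1.18 with the stricter filter, 3.41 without cluster 10 and 1.47 without dendritic cells; in B 0.34 without cluster 10 and 0.82 with separate clustering. Endothelial-like share in A: 0.24 with cluster 8, 0.19 with doublets kept and 0.0908 with the stricter filter; in B 0.26 with separate clustering. T-like share with separate clustering: -1.97 in A and 0.36 in B. Kupffer-like share in A with the stricter filter: -0.57.

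TMM factors in A gave neutrophil-like Gsdmd -2.99, p53 -0.46, interferon-stimulated genes -3.14 and monocyte recruitment 0.0246, endothelial-like p53 2.59 and monocyte-like dissociation stress 0.10. In B they gave endothelial-like p53 -0.0214 and Kupffer-like p53 -0.25, identity 0.0123 and NRF2 0.10. Doublets kept gave in A neutrophil-like p53 0.59 and sinusoidal identity 0.92 and T-like interferon-stimulated genes -0.967, and in B Kupffer-like p53 -0.19 and T-like granules -0.49 and neutrophil activation -0.20. The mean of per-cell CPM gave in A dissociation stress 0.0154 in endothelial-like and -0.00158 in Kupffer-like cells and T-like interferon-stimulated genes -1.10, and in B neutrophil-like interferon-stimulated genes 0.71 and monocyte recruitment 0.14, and Kupffer-like Gsdmd 2.92 and stellate genes -0.0236.

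Members with at least 100 UMIs gave in A neutrophil-like interferon-stimulated genes -2.99 and monocyte-like fatty acid genes 0.0799, and in B neutrophil-like interferon-stimulated genes 0.0639, monocyte-like granules -0.21 and T-like hepatocyte transcripts 0.33. The stricter filter gave monocyte-like dissociation stress 0.0632 in A. Without cluster 10 monocyte-like cells had in A p53 -0.42, interferon-stimulated genes -2.09, cGAS-STING 0.37 and lipid-associated macrophage genes 0.26. Without dendritic cells they had interferon-stimulated genes -3.31 in A. Without cluster 10 they had in B p53 -0.0516, interferon-stimulated genes -0.00717, inflammatory genes -0.34, inflammasome genes -0.23, cGAS-STING -0.0580, cytotoxic genes -1.15, neutrophil activation -0.33 and NRF2 -0.145.

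The named genes that moved furthest were, in monocyte-like cells without cluster 10, Cxcl9 and H2-Ob in A, whose limits were then lower or not to be had, and Cxcl10 (1.82) and Ifi205 (1.79) in B. Saa3 in A was 6.02 as a mean of per-cell CPM, 6.69 at resolution 2, 6.78 without cluster 10 and 6.82 without dendritic cells, and Cxcl10 in B was 4.88 with doublets kept. In A the mean of per-cell CPM gave Kupffer-like Ccl9 5.19, and doublets kept gave neutrophil-like Prr5l -6.40. Endothelial-like Saa1, Saa2, Ahsg and Apoa2 in B and Kupffer-like Ttc39c in A moved too, each by less than Ccl9. Without cluster 10 the control keeps 41 monocyte-like cells, under the minimum of 50.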

Other observations

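The tests of exchanged labels, of scaling and of a control-animal state for the interferon-stimulated genes, and of cluster 10 were chosen only after the result was seen. So was the list of glucocorticoid-induced genes as a question, though its outcome was not known when its criteria were set.

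Gsdmd was lower in the library labelled FL_IR than in both others. Of the measured genes, 0.0707 percent (6 of 8487) were at least 2-fold lower there than in both others in all 5 classes: Gsdmd, H2-Ab1, H2-Aa, H2-Eb1, Cd74 and Gm47283. Levels were scaled to class totals and few genes could meet that condition, so this share decides little about scaling or depth. Against FL_control the median log2 ratio of all genes lay between -0.58 and -0.03 over the classes, and that of Gsdmd between -3.64 and -1.49. For dHep_IR against FL_IR the medians lay between -0.16 and -0.003, and Gsdmd between 1.39 and 3.03. These values argue against a scaling shift as the source of the Gsdmd pattern. Exchanged labels with a deletion in hepatocytes only are argued against as well, since the lowest fold of dHep_IR over FL_IR among the 5 other classes was 2.62 (2.18 to 3.17). Exchanged labels with a deletion in all cells may explain it, and stay open, because the idea came from these values: the part of the control level kept in FL_IR was at most 0.356 (0.296 to 0.426) and at least 0.0804 (0.0634 to 0.102). A first criterion, equal parts kept in all classes, was not met, and it was replaced after that outcome by one that asks only for all classes to lie far below control, since transcripts left by a deletion need not be equally stable in each class. No biological explanation was tested.

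Interferon-stimulated genes were higher in the library labelled FL_control than in FL_IR in all 5 classes. Free RNA shared by all classes is argued against only in part. After the level of the lowest class was taken off, 69.8 percent of members in the other classes (88 of 126) stayed 2-fold above FL_IR. That step takes the same CPM off every class, while free RNA weighs more in cells with fewer UMIs. The median UMIs per cell of FL_control ran from 3481 in neutrophil-like to 10324.5 in monocyte-like cells. Free RNA can therefore not be excluded in the shallower classes. Scaling of the class sums is argued against too, since the highest median under the alternative scalings was -0.51. A state of the 1 control animal or preparation, such as an infection, could also give this pattern and cannot be told apart from irradiation, because there is 1 control library, which also stood apart in haemoglobin transcripts (Hbb-bs at 600 CPM against 2.28 in FL_IR and 18.3 in dHep_IR).

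Interferon-stimulated genes were higher in monocyte-like cells of the library labelled dHep_IR than of FL_IR. Within cluster 7 the median was 0.0704 above matched lists. This cannot decide whether a larger share of cluster 10 accounts for the pattern. Clusters 7 and 10 were drawn from the same expression values, which can sort cells with more of these transcripts into cluster 10. The test also nearly repeats the median without cluster 10, since almost all cells then left lie in cluster 7. A change in the make-up of the class and a change of state in the same cells cannot be told apart. Dendritic cells counted with the class are argued against, since the median stayed at 1.23 after 101 such cells were removed, 4 of FL_IR and 97 of dHep_IR. That test was redone after a first version had removed no cells. Why cluster 10 holds 544 cells in dHep_IR and 30 in FL_IR was not tested.

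A hypothesis from Zbtb16 and Fkbp5, which glucocorticoids induce, was that genes induced by glucocorticoids may be higher in the library labelled FL_IR than in FL_control. A list without these genes met both criteria, a median at least 0.5 above matched lists and a percentile above the limit set, in 2 of the 5 classes, where 4 had been asked for. The median was 0.96 in endothelial-like and 1.21 in Kupffer-like cells above matched lists. It was 0.54 above them in neutrophil-like (percentile 97.46), 0.41 in T-like (99.82) and 0.21 in monocyte-like cells (93.12). In neutrophil-like cells the median itself was -0.04 and that of matched lists -0.58. There 3 of 18 members were at least 2-fold higher and 7 at least 2-fold lower. The list also holds Mt1, Mt2 and the dissociation stress genes Dusp1 and Zfp36. In dHep_IR against FL_control the values above matched lists were 0.62 in endothelial-like (percentile 99.86) and 0.72 in T-like cells (percentile 100). They were 0.34 in Kupffer-like (98.4), 0.09 in monocyte-like (71.7) and -0.09 in neutrophil-like cells (39.6). The hypothesis stays undecided.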
